A study of Mus musculus with 3 samples.

How the data were processed

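RNA from mouse embryonic stem cells was analysed on 3 1-colour arrays, 1 each for wildtype, Pcgf6KO and Pcgf6KO with Flag-tagged Pcgf6. The groups come from the genotype labels. A source field of the labels names muscle, whereas the cell type field gives embryonic stem cells, and the latter was used. Per the labels' protocols, the cells were grown on inactivated fibroblasts and RNA was extracted with TRIzol, so the RNA can contain feeder transcripts.

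Per the file headers, the scanner output is the spot intensity on a linear scale, extracted with Agilent Feature Extraction 11.5.1.1. The submitters' processing notes name version 10.7 instead. The deposited processed intensity is background-subtracted and always above 0. The value table of the series was compared with the scanner values. For each of the 3 arrays, 55249 of 55249 probes with a single spot held the processed signal within a relative tolerance of 1e-06, so that table is linear, unscaled and uncentred, with no ratio and hence no direction. Its column medians were 243, 273 and 313.

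Each array held 62976 spots, of which 59305 were not controls. Control spots and the 141, 158 and 192 spots marked as outliers on the wildtype array, the Pcgf6KO array and the array labelled as re-expressing were left out, and 0 spots were saturated. Spots of one probe were averaged. The main value was log2 of the processed signal minus the array's 75th percentile. A probe counted as measured where most of its kept spots were well above background. A gene was read from its brightest probe among probes measured on at least 1 array. Median processed signals were 272, 308 and 340, and the lowest signals well above background were 52.7, 53.4 and 103. The number of arrays limits the precision.

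The scanner files carry accessions rather than gene symbols. Accessions were matched without versions to RefSeq genes of GRCm38.p6, which named 26762 of 55681 probes and gave 20274 genes, of which 16048 were measured on at least 1 array. The remaining 28919 probes were unnamed here. The array design is annotated on mm9, so no coordinates from GRCm38.p6 were used, only its gene order in the test of neighbouring genes. For 5401 genes with several probes, agreement was checked. Among genes with at least 2 measured probes, of which at least 1 passed 2-fold, all probes had the same sign in 217 of 229 genes for Pcgf6KO against wildtype, 432 of 518 for the array labelled as re-expressing against Pcgf6KO and 292 of 368 against wildtype.

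With 1 array per group no test was possible, and a fixed 2-fold rule was used. Where 1 of 2 arrays was not well above background, the difference was given as a bound against the higher of that array's lowest signal well above background and the gene's own signal. These bounds are written as "at least N-fold". The median of each of 21 gene lists was computed with members at their bound, and compared with 10000 random lists matched on mean expression in 20 bins, which describes these arrays only. The lists were PRC1.6, other PRC1 and PRC2 subunits, germline and meiosis, pluripotency, primed or epiblast, mesendoderm, endoderm, neural ectoderm, trophoblast, 2-cell stage, Hox, imprinted and Y-linked genes, fibroblast markers, p53 targets, stress response, interferon-stimulated, housekeeping, immediate early, and glycolysis and hypoxia genes. Of their 458 symbols 10 were updated to current names and 1 was not found.

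The lists, the alternatives and the rule for naming genes were fixed before the data were examined, except where stated. The rule took Pcgf6, the 12 highest and 12 lowest differences of each comparison among genes at or above the median signal, and the 5 largest bounds in each direction. It also took the 12 genes in each direction in which Pcgf6KO stood furthest from both other arrays, up to 4 members per list and comparison, and 8 canonical pluripotency and germline genes. Predicted genes were counted but not named. Some genes that the rule selects are not reported here.

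The calls were tested on simulated data for Pcgf6KO against wildtype, with 14152 genes and the spread of repeated spots. Of 200 genes changed 2-fold, 51.5% passed the 2-fold rule. All of those changed 3-fold or 4-fold passed, and 0.00% of those changed 1.5-fold. No unchanged gene was called, 0 in each run.

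Alternatives were normexp background correction in limma 3.58.1 (offset 50), quantile normalization, scaling to the median or the 75th percentile of probes measured on all arrays, the deposited value table, bright genes only, no filter on dim probes, the mean over probes, outlier spots kept, and thresholds of 1.5-fold and 3-fold. The mean spot signal planned for normexp was replaced by the median spot signal, which these files carry. The deposited table without scaling was added after the data were examined. Slide as a block was not run, because slide 2 holds only 1 array. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and R 4.3.3.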

Results

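Gene expression was measured in mouse embryonic stem cells grown on feeder fibroblasts that had been inactivated with mitomycin C. There were 3 groups with 1 array each: wildtype cells, cells in which Pcgf6 had been edited with Cas9 (Pcgf6KO), and edited cells that had received Flag-tagged Pcgf6 by lentivirus. Pcgf6 is a Polycomb group RING finger protein and the defining subunit of the variant Polycomb repressive complex PRC1.6. RNA was labelled with Cy3 and hybridised to a 1-colour Agilent mouse array with 55681 probes. With 1 array per group no difference has a replicate check, no p-value is given, and the number of arrays limits the precision. Differences are in log2 units after scaling each array to its 75th percentile, and "higher" or "lower" refers to these 3 arrays.

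The share of probes well above background was 65.3% for wildtype, 66.0% for Pcgf6KO and 60.7% for the array labelled as re-expressing. The SD of the negative controls was 8.80, 9.09 and 16.9 signal units on the same arrays. Wildtype and Pcgf6KO lay on slide 1, and the third array lay alone on slide 2. Repeated spots of one probe differed with an SD of 0.09 log2 units within each array, and 0.13 for a difference between single spots of Pcgf6KO and wildtype.

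Pcgf6 itself was read by 1 probe, matched to NM_027654. Its scaled level was 1.87 in wildtype, 0.84 in Pcgf6KO and 0.43 on the array labelled as re-expressing. It was thus lower by -1.03 in Pcgf6KO than in wildtype, and it was not higher after the labelled re-expression, where the difference from Pcgf6KO was -0.42. Where this probe lies relative to the edit and to the introduced sequence is not given in the sources used here, so its level does not settle either label. The third array is therefore called the array labelled as re-expressing, and every direction drawn from it rests on that label.

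The first comparison, Pcgf6KO against wildtype, asks which transcripts differ between the edited and the wildtype culture, feeder RNA included. The germline list was higher in Pcgf6KO and the list of fibroblast markers was lower, although many members of each differed by less than 2-fold. Xlr4b, of the X-linked lymphocyte-regulated family, was higher by 6.36, and the cancer-testis gene Luzp4 by 6.35. Mgp, which encodes the calcification inhibitor matrix Gla protein, was 128-fold lower. The core pluripotency factors Pou5f1, Nanog and Sox2 differed by only -0.20, -0.10 and -0.07.

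Among 14997 genes measured on both arrays, 869 were at least 2-fold higher and 422 at least 2-fold lower in Pcgf6KO, so 67.3% of these were higher. Among 15366 measured probes without a gene name the balance was the opposite, with 510 higher and 697 lower. These are counts of probes rather than genes, and several probes can read one region. A further 179 genes were measured on 1 array only and at least 2-fold higher in Pcgf6KO, and 143 at least 2-fold lower. Among named genes at or above the median signal, the highest after Xlr4b and Luzp4 were Xlr4a with a difference of 5.55, Xlr3a with 5.10, Ct55 with 4.86 and Xlr3b with 4.75. They were followed by the reproductive homeobox gene Rhox13 with 3.90, Tdrkh, which takes part in piRNA biogenesis, with 3.87, the metal transporter Slc39a8 with 3.73 and the meiotic recombination gene Tex11 with 3.35. Fmr1nb and Tex101 were higher by 2.88 and 2.87. Xlr5c was not well above background in wildtype and was at least 66.1-fold higher in Pcgf6KO, and Xlr5b at least 46.6-fold. The same kind of bound was 16.2-fold for Nts, the neurotensin gene, and 10.4-fold for both Scel and Ly6k. Members of the Xlr family are near-identical, so their probes may share transcripts.

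On the lower side and at or above the same signal, the proliferin gene Prl2c5 differed by -6.99, the cholecystokinin gene Cck by -6.21, Tm4sf1 by -5.30 and Prl2c1 by -5.05. Inhba, the inhibin beta A subunit, differed by -4.71 and the cornified envelope gene Lce1h by -4.09. Fbln2, an extracellular matrix fibulin, was lower by -3.74 and the chemokine gene Ccl2 by -3.29. Lce1c and Cd99 both differed by -2.85. Lce1g, Serpinb2 and Mcpt8 were well above background in wildtype only and were at least 79.5-fold, 70.2-fold and 69.6-fold lower in Pcgf6KO. The mesenchymal homeobox gene Prrx1 was at least 37.2-fold lower. Because the cells were grown on feeder fibroblasts, lower transcripts may be feeder RNA, which these arrays cannot separate from stem cell RNA. Prl2c5, Cck, Tm4sf1 and Inhba were, like the fibroblast markers, also lower than wildtype on the array labelled as re-expressing.

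Of the germline and meiosis list, 43 of 48 genes on the array were measured on both arrays. In Pcgf6KO 20 were at least 2-fold higher and 3 at least 2-fold lower, and 3 more were higher as bounds. The list median was 0.98 (95% order-statistic interval over genes 0.57 to 1.72), above the medians of all 10000 random lists matched on expression. Tdrkh, Tex11, the meiotic gene Mei1 with 3.12 and the testis bromodomain gene Brdt with 2.92 led the list. Mael, a piRNA pathway gene, was higher by 2.19, whereas Ddx4, the germ cell helicase, and Dazl, a germ cell RNA-binding protein, differed by 0.91 and 0.78. The 3 lower members were Hsf2bp with -2.41, Meiob with -1.81 and Rpl10l with -1.05, the last of which was named after its value was seen.

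Trophoblast genes had a median of 0.58 at percentile 99.99, with 6 of 17 measured members at least 2-fold higher and 0 lower. Examples were the homeobox genes Rhox6 with 1.68 and Rhox9 with 1.64, and Hand1 with 1.48. Interferon-stimulated genes had a median of 0.47 at percentile 99.98, with 7 of 20 members higher and 0 lower. The list interval ran from -0.13 to 1.197. The chemokine gene Cxcl10 was higher by 2.253, the RNA sensor Ifih1 by 1.79, the immunoproteasome gene Psmb8 by 1.64 and the GTPase gene Gbp2 by 1.62. Among 2-cell stage genes, 3 of 10 measured members were higher, including Zscan4f with 2.92 and Zscan4c with 2.73, and Tcstv3 was at least 6.71-fold higher, but the list median of 0.29 had an interval from -0.24 to 2.73 and was -0.25 among bright genes only.

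Fibroblast markers were lower, with a median of -0.80 (-1.97 to -0.46) at percentile 0.00. Of 31 markers measured on both arrays 12 were at least 2-fold lower and 0 higher, with 2 more lower as bounds. The cross-linking enzyme gene Lox differed by -4.04, followed by Fbln2 and Ccl2, and the collagen gene Col3a1 by -2.48. The germline and fibroblast differences were read from the same pair of RNA samples and went in opposite directions, with medians of 0.98 and -0.80. Whether the fibroblast difference is feeder signal was not settled. Hox genes had a median of -0.82 at percentile 0.00, with 5 of 22 measured members lower and 0 higher, and 5 lower and 1 higher as bounds. Hoxc9 differed by -1.86 and Hoxd10 by -1.72. Whether the lower Hox levels come from feeder or stem cell RNA was not settled either.

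Pluripotency genes had a median of -0.22 at percentile 0.18, and 1 of 30 members, Gbx2 with -1.33, passed 2-fold. The median was -0.31 for primed or epiblast genes, -0.22 for endoderm genes and -0.22 for immediate early genes. Their percentiles were 0.20, 2.18 and 1.53. PRC2 subunits with -0.17 and glycolysis and hypoxia genes with -0.14 lay at percentiles 10.69 and 23.29, so such medians were common among random lists. Mesendoderm genes had a median of 0.21 at percentile 79.72, with Wnt3 higher by 2.02. Medians of -0.03 for other PRC1 subunits, 0.02 for stress response genes, 0.02 for imprinted genes, 0.01 for neural ectoderm genes and 0.02 for housekeeping genes changed sign under at least 1 scaling or background alternative. Those of -0.08 for PRC1.6 subunits and -0.09 for p53 targets did so only in the unscaled deposited values. Among PRC1.6 subunits only Pcgf6 passed 2-fold. The 3 measured Y-linked genes had a median of 0.51 at percentile 95.8.

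Simulated unchanged arrays with the spread of repeated spots gave 0 genes past 2-fold, but that spread leaves out differences between cultures and RNA preparations. Without scaling, the deposited values gave 1079 higher and 310 lower genes, or 77.7% higher, and the median of all genes was then shifted to 0.11, whereas bright genes only gave 57.0% higher.

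**Figure D1:**
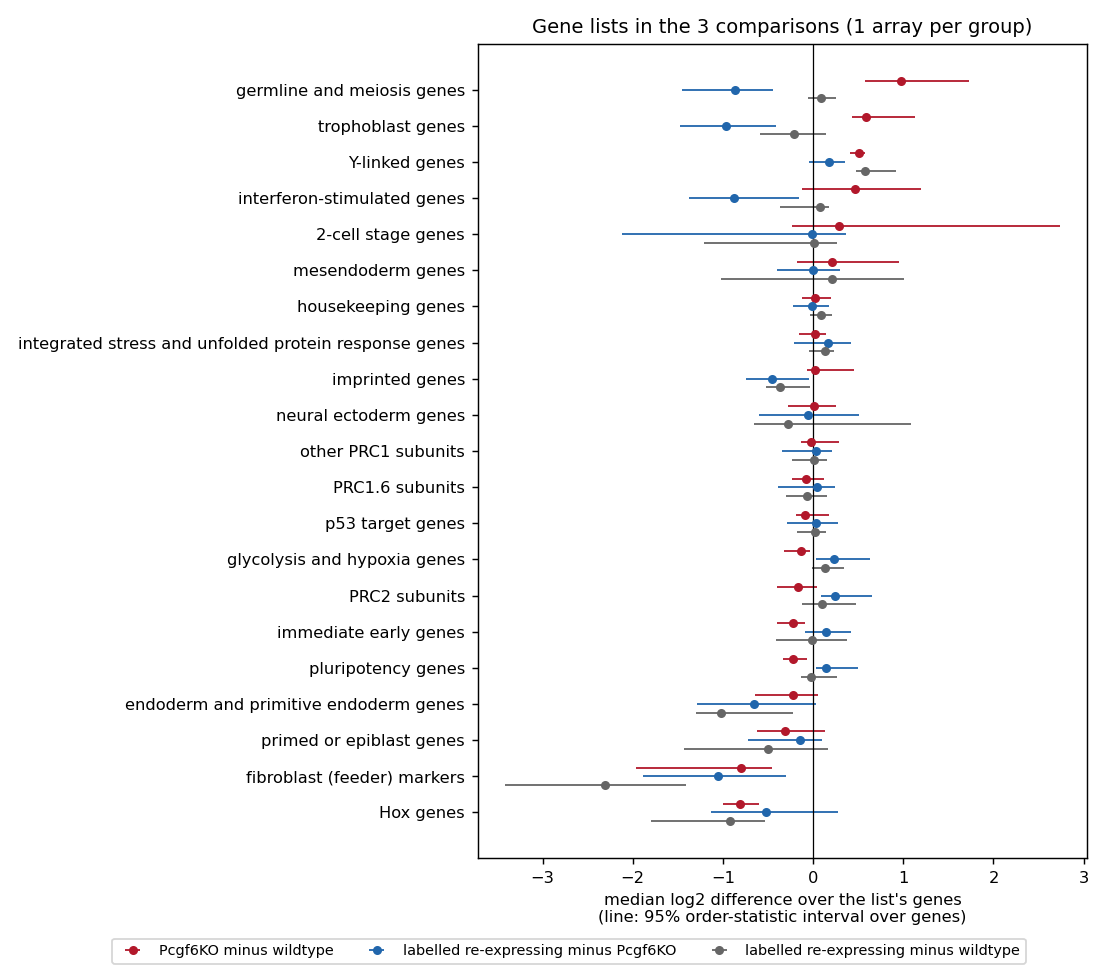
Median log2 difference of each gene list (points) in the 3 comparisons, with 95% order-statistic intervals over genes as lines (for the 3 Y-linked genes the line is their whole range). Germline genes sit at 0.98 for Pcgf6KO minus wildtype and at -0.86 for the array labelled as re-expressing minus Pcgf6KO, whereas fibroblast markers lie below 0 in all 3 comparisons.

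The second comparison, the array labelled as re-expressing against Pcgf6KO, asks which levels differ between these 2 arrays, whose labels differ in the introduced Pcgf6. The lists of germline, trophoblast and interferon-stimulated genes and of fibroblast markers had medians below 0, although many of their members differed by less than 2-fold and some germline genes were higher. Luzp4 was lower by -4.35, Ct55 by -4.09, Tdrkh by -3.82 and Xlr3a by -3.53.

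Of 14241 genes measured on both arrays, 773 were at least 2-fold higher and 1192 at least 2-fold lower on the array labelled as re-expressing, with 200 and 387 more as bounds. Among genes at or above the median signal, the lowest after those above were the synaptic gene Slitrk5 with -3.47, Gatm, of creatine synthesis, with -3.19, the matrix gene Tgfbi with -3.18, Gng11 with -3.16 and Anxa3 with -3.13. Xlr4b followed with -3.12, the enkephalin precursor gene Penk with -3.05 and Paqr9 with -3.02. Zscan4f and Zar1, a maternal-effect gene, were not well above background on the array labelled as re-expressing and were at least 29.1-fold and 28.7-fold lower there. The bounds were 22.4-fold for Rbm46, 15.4-fold for Zscan4c and 14.5-fold for Zscan4a.

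The highest differences at or above that signal were 2.45 for Ddo, the D-aspartate oxidase gene, 2.35 for Septin1, 2.16 for both Kcnk4 and the phosphatase gene Inpp5d, 2.11 for the homeobox gene Hesx1 and 2.09 for Ms4a10. Cfp, the complement properdin gene, was higher by 2.08, Ptprcap by 1.998, Tekt4 by 1.94, the Wnt deacylase gene Notum by 1.93 and Anxa8 by 1.89. Zfp467 was higher by 1.97 on its brightest probe, but lower by -0.80 as a mean over its probes. Serpinb6e was at least 23.1-fold higher, Prss21 at least 11.7-fold and Klrb1b at least 8.78-fold.

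The germline list had a median of -0.86 (-1.46 to -0.45) at percentile 0.00, with 17 of 41 members at least 2-fold lower and 4 higher. The 4 higher members were Hsf2bp with 2.66, Meiob with 1.87, Stag3 with 1.37 and Tex14 with 1.23, of which Stag3 and Tex14 were named after their values were seen. Mei1 was lower by -3.19, Brdt by -2.82 and Cpeb1 by -2.75. Trophoblast genes had a median of -0.97, with 8 of 16 members lower, Cdx2 among them with -2.82. Interferon-stimulated genes had a median of -0.88, with 7 of 18 lower and 1 higher, and Cxcl10 at -2.52. Fibroblast markers had a median of -1.06, with 14 of 28 lower and 0 higher, including Twist2 with -2.86, Col3a1 with -2.82, Col1a2 with -2.73 and Dcn, the decorin gene, with -2.63.

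Endoderm genes had a median of -0.65, with Dab2 at -3.47, but 0.078 among bright genes only. Imprinted genes had a median of -0.46, with Ndn at -2.16 and Igf2 at -2.13. Hox genes had a median of -0.52 at percentile 4.58, with 12 of 39 measured on both arrays. Primed or epiblast genes had a median of -0.15 at percentile 6.94. Medians above 0 were 0.25 for PRC2 subunits, 0.23 for glycolysis and hypoxia genes and 0.16 for stress response genes. They were 0.15 for pluripotency genes, 0.14 for immediate early genes and 0.18 for the Y-linked genes. In this order their percentiles among the random lists were 97.22, 97.56, 88.6, 87.15, 87.8 and 75.1. Random lists thus reached such medians as well, least often for PRC2 subunits and glycolysis and hypoxia genes. PRC1.6 subunits with 0.04, other PRC1 subunits with 0.03, p53 targets with 0.03, mesendoderm genes with 0.00, housekeeping genes with -0.01, neural ectoderm genes with -0.05 and 2-cell stage genes with -0.01 changed sign under at least 1 scaling or background alternative. Of the 2-cell stage genes, 5 were at least 2-fold lower as bounds and 0 higher. Group and slide cannot be told apart in this comparison, because the array labelled as re-expressing lay alone on its slide.

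The return of levels towards wildtype was counted over 1021 genes that differed at least 2-fold between Pcgf6KO and wildtype and were measured on all 3 arrays. On the array labelled as re-expressing 704 of them, or 69.0% (95% exact binomial interval 66.0% to 71.8%), had moved back by at least 0.5 of the difference. This held for 543 of 681 genes higher in Pcgf6KO and for 161 of 340 lower genes, or 79.7% and 47.4%. The lower genes can include feeder transcripts. The 95% interval above treats genes as independent and covers no variation between arrays. The share back was 50.1% for simulated arrays with equal noise. The 47.4% of the lower genes was not above that value, so a return beyond it was seen only for the higher genes. Because genes were chosen for a large Pcgf6KO difference, part of the return can arise from the shared Pcgf6KO array, and how much was not measured. With the arrays in other roles the share was higher in 1 case: of 1358 genes that differed between wildtype and the array labelled as re-expressing, 76.8% lay back towards wildtype in Pcgf6KO. Of 1926 genes that differed between Pcgf6KO and the array labelled as re-expressing, 57.5% lay back towards Pcgf6KO in wildtype. Exchanging the start and changed arrays gives the complement of each share over the same genes. The resulting 31.0%, 23.2% and 42.5% are therefore no separate comparison.

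Pcgf6KO stood at least 2-fold above both other arrays in 471 genes and below both in 110. The array labelled as re-expressing stood above both in 426 genes and below both in 444, and wildtype in 144 and 98. Genes in which Pcgf6KO stood highest included Mageb4, with a difference of 5.11 from wildtype and -3.35 on to the array labelled as re-expressing, Htr5b with 3.06 and -3.09, St8sia6 with 3.49 and -3.01, Tcam1 with 3.20 and -2.97, and Rhox2c with 2.98 and -2.88. Genes in which it stood lowest included Septin1 with -2.67 and 2.35, Myo1g with -2.63 and 2.15, and Gjb1 with -2.04 and 2.47. Among 3664 genes with 2 measured probes, 62 stood highest in Pcgf6KO on the brighter probe and 43 of them on both.

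The 471 genes that were higher in Pcgf6KO than wildtype and lower again compare with 57.1 for independent lists of the same sizes, and the 110 in the opposite direction with 17.8. Both differences contain the Pcgf6KO array, and with 1 array it cannot be split, so part of the excess may come from it. Across genes, which are not independent replicates, the 2 differences had a Pearson correlation of -0.55 and a covariance of -0.23. Unchanged arrays with the spread of repeated spots gave -0.48 and -0.01, and arrays with equal noise of the observed size gave -0.50 and -0.21. Differences from wildtype that persisted were also more frequent than for independent lists. Both other arrays were at least 2-fold lower than wildtype in 144 genes against 16.3, and higher in 98 against 32.7. These overlaps share the wildtype array, so part of their excess may come from that array.

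**Figure D2:**
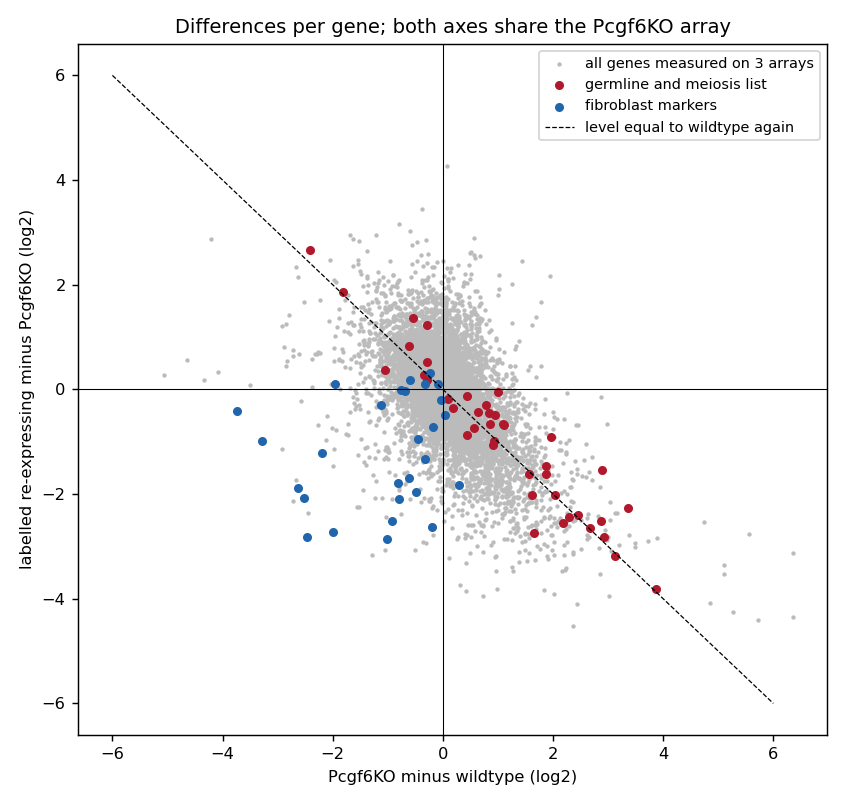
Log2 difference of Pcgf6KO minus wildtype (x axis) against the array labelled as re-expressing minus Pcgf6KO (y axis) for 14152 genes measured on all 3 arrays, with germline genes in red, fibroblast markers in blue and a dashed line where the level equals wildtype again. Tdrkh lies close to the dashed line at 3.87 and -3.82, and Col3a1 lies below it at -2.48 and -2.82.

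The third comparison, the array labelled as re-expressing against wildtype, asks what still differs. The list of fibroblast markers was lower on the array labelled as re-expressing, and the germline list was close to wildtype. Col3a1 was lower by -5.29, Col1a2 by -4.73 and the smooth muscle actin gene Acta2 by -4.52. Several Xlr genes stayed above wildtype, with Xlr3b higher by 2.22 and Xlr5c at least 16.2-fold.

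Among 14193 genes measured on both arrays, 697 were at least 2-fold higher and 682 at least 2-fold lower, with 212 and 297 more as bounds. Besides the collagens and Acta2, the lowest at or above the median signal were the muscle ankyrin repeat gene Ankrd1 with -4.85, the growth factor gene Csf1 with -4.79, Prl2c1 with -4.78, S100a4 with -4.60, Gng11 with -4.45, Ifi27 with -4.40, Ccl2 with -4.27, Fbln2 with -4.15 and Lce1h with -3.76. Inhba, Tm4sf1 and Prl2c5 were not well above background on the array labelled as re-expressing and were at least 251-fold, 202-fold and 199.6-fold lower. The bounds were 82.8-fold for Mgp and 61.7-fold for Cck. The highest at or above that signal were the pepsinogen gene Pga5 with 2.80, Fmr1nb with 2.73, Ddo with 2.45, Zcchc10 with 2.24, Hesx1 with 2.20, the glutathione transferase gene Gstm3 with 2.18, Kcnk4 with 2.17, Tekt4 with 1.96, Krtdap with 1.90 and the aldehyde dehydrogenase gene Aldh3a1 with 1.87. Krtap11-1 was at least 17.6-fold higher. Zfp467 was higher by 2.33 on its brightest probe and lower by -0.89 as a mean over its probes.

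Fibroblast markers had a median of -2.31 (-3.41 to -1.41), with 19 of 28 members at least 2-fold lower and 0 higher. The level was nevertheless close to wildtype for Fn1, the fibronectin gene, with 0.01, which was named after its value was seen. Germline genes had a median of 0.08, which was below 0 under quantile normalization, with 3 of 41 members higher, among them Hormad2 with 1.34 and Tex11 with 1.08, 1 lower, Cpeb1 with -1.10, and 1 more lower as a bound. Endoderm genes had a median of -1.03, or -0.18 among bright genes only, Hox genes -0.92, primed or epiblast genes -0.50 and imprinted genes -0.37. Feeder and stem cell RNA cannot be separated in these lists either. Neural ectoderm genes had a median of -0.28 at percentile 5.48, with 4 of 15 higher and 3 lower, Sox1 at -2.95 and Hes5 at 1.95. The 3 Y-linked genes had a median of 0.58 at percentile 96.8, and mesendoderm genes 0.21 at percentile 86.57.

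Interferon-stimulated genes with a median of 0.08, pluripotency genes with -0.03, 2-cell stage genes with 0.01, p53 targets with 0.03 and immediate early genes with -0.01 changed sign under at least 1 scaling or background alternative. Trophoblast genes with -0.21 and PRC1.6 subunits with -0.06 did so only in the unscaled deposited values. The medians for other PRC1 subunits, PRC2 subunits, stress response genes, housekeeping genes and glycolysis and hypoxia genes were 0.01, 0.10, 0.13, 0.09 and 0.14. In this order their percentiles among the random lists were 72.69, 91.47, 96.67, 92.5 and 98.91. Among pluripotency genes Prdm14, a germ cell and pluripotency regulator, was higher by 1.66 and Tcl1 by 1.15, and Gbx2 was lower by -1.09. Without scaling the deposited values gave 1075 higher and 450 lower genes, or 70.5% higher against 50.5% in the scaled data, with the median of all genes at 0.22. Bright genes only gave 89 higher and 144 lower, or 38.2% higher, so the balance depends on these choices, and slide and group cannot be told apart.

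**Figure D3:**
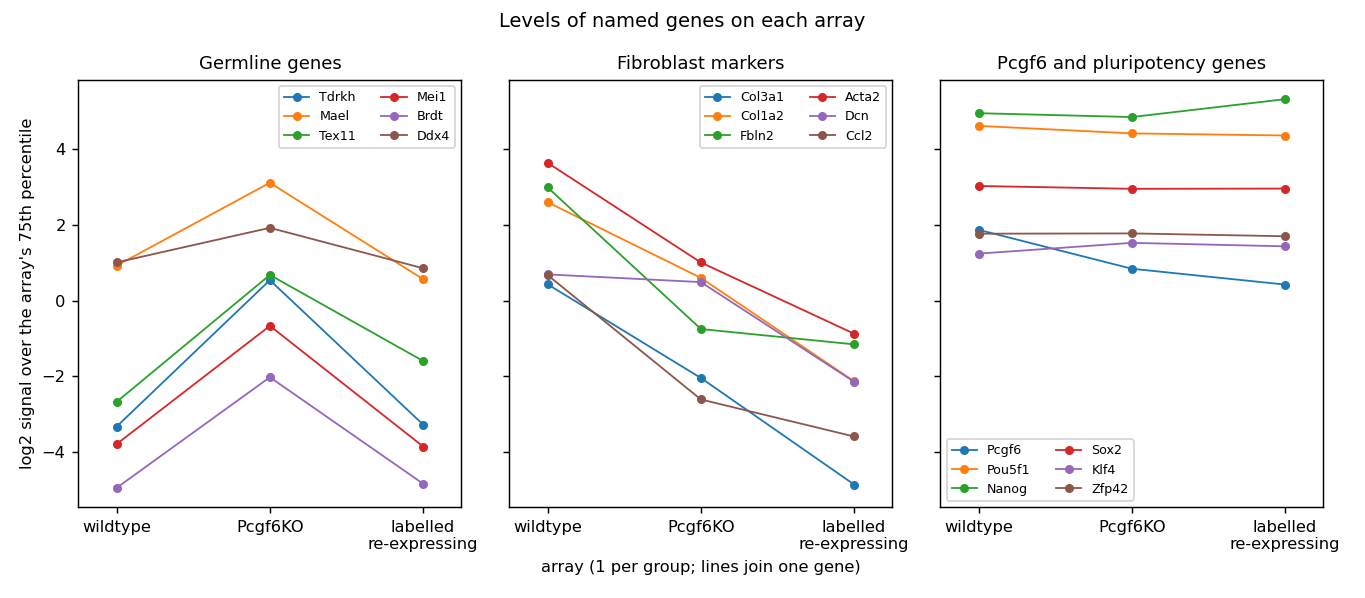
Scaled log2 signal (y axis, relative to each array's 75th percentile) of named genes on the 3 arrays (x axis, 1 array per group), with lines joining the values of a gene. The plotted germline genes are highest in Pcgf6KO, Col3a1 goes from 0.43 in wildtype to -4.86 on the array labelled as re-expressing, and Pcgf6 reads 1.87, 0.84 and 0.43.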

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

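The tests of feeder share on the germline genes, both tests of the fibroblast markers, the separate tests of genes higher and lower on the array labelled as re-expressing, the test of its slide, and the use of random lists against noise were chosen after the results were seen.

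Probes without a gene name were outside the comparisons and were counted per probe rather than per gene. Of 15366 such probes measured on both arrays, 510 were at least 2-fold higher in Pcgf6KO than in wildtype, and 697 at least 2-fold lower. In 163 of 13900 measured on all 3 arrays Pcgf6KO was at least 2-fold above both others, and in 222 below both. Some of these probes are named by the array design for mm9 regions. A probe for chromosome 1 from 87613025 to 87631604 on the forward strand was higher by 2.54 in Pcgf6KO and lower by -3.04 on the array labelled as re-expressing. One for chromosome 19 from 16090063 to 16103160 on the reverse strand differed by 3.05 and -2.49. On the lower side, a probe for chromosome 13 from 98281158 to 98285757 on the forward strand differed by -2.10 and 3.40. A probe for chromosome 7 from 91558475 to 91733625 on the forward strand differed by -4.76 and 2.20, but only 1 of the region's 3 measured probes stood apart in this way.

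The germline list was higher in Pcgf6KO and near wildtype again on the array labelled as re-expressing. Scaling or background correction as the whole source is argued against by the list median, which was at least 0.91 under each of 5 alternatives. A lower feeder share would raise all stem cell transcripts alike. Scaling can remove such a shared rise, so the pluripotency median of -0.22 alone cannot test it. Scaling shifts all genes of an array equally, however, so a shared rise would still give both lists the same difference. Germline genes were instead at 0.98 (0.57 to 1.72) and pluripotency genes at -0.22 (-0.33 to -0.06), which argues against it as the whole source. Against wildtype, fibroblast markers were at -2.31 on the array labelled as re-expressing, but germline genes were at 0.08. Noise of single probes on the Pcgf6KO array as the whole source is argued against by 6 members with a second probe, whose median there was 0.85 (range -1.35 to 3.60), and by the list interval of 0.57 to 1.72, above the central 95% of random lists (-0.11 to 0.16). Loss of Pcgf6 undone by re-expression stays open as a hypothesis. It was untested, because the single Pcgf6 probe, not higher on the array labelled as re-expressing, cannot settle that label. A difference between single cultures cannot be excluded with 1 array per group.

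As a list, fibroblast markers were lower in Pcgf6KO than in wildtype and lower again on the array labelled as re-expressing. A smaller share of feeder RNA of one composition would give markers lost on the last array one shared difference between Pcgf6KO and wildtype. However, among 9 markers measured on all 3 arrays and at least 8-fold lower on the last than in wildtype, this difference had an SD of 0.93. It ranged from -3.74 for Fbln2 to -0.93 for Col1a1. An effect of Pcgf6 loss stays open, because the median of -1.06 for the array labelled as re-expressing minus Pcgf6KO restates the pattern. The single Pcgf6 probe, which was not higher there, does not settle that label either. Feeders that differed in both number and state also remain a candidate explanation. Of 34 markers on the array 28 were still measured on the array labelled as re-expressing and 0 belong to another list, and abundant ones such as Vim, at 4.06, 3.37 and 3.33, may also come from the stem cells.

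The array labelled as re-expressing stood apart from both others in 870 genes, against 581 for Pcgf6KO. Its higher background may account for part of this. Among bright genes it stood apart in 152 genes against 118, a ratio of 1.29 (95% exact interval 1.01 to 1.65). This leaves the total open, and such intervals treat genes as independent. For genes higher than both others the ratio was 0.54, from 50 against 93, and only 14 of 55 such genes passed on 2 probes. Over all genes the counts were already 426 against 471. For genes lower than both others the ratio was 4.08 (2.61 to 6.60), from 102 against 25, and over all genes the counts were 444 against 110. That excess was thus also seen among genes bright on at least 1 array, although such genes can be dim on the array labelled as re-expressing. Fibroblast markers were also lower there, with medians of -1.06 against Pcgf6KO and -2.31 against wildtype. Whether feeder RNA contributed to the excess was not tested. Both ratios divide by the counts of Pcgf6KO, which itself stood higher far more often than lower, so neither decides on background. Slide and group cannot be told apart, as 1 array lay on that slide.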

How the results depend on the processing

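The deposited table without scaling was chosen after the data were seen. No paired analysis was possible because each group has 1 array, which also rules out leaving out a replicate. Slide as a block was not run. A count was taken as moved when it differed by more than 1.5 times, and a list median when it left its interval over genes. Among main results 915 values were unmoved and 104 moved, and among single named genes 5108 were unmoved, 720 moved and 2 took the opposite sign. The deposited table scaled in the same way holds the main signal for every probe with a single spot. Its unmoved values, counted above, are therefore no separate check. Quantile normalization, scaling to the median and outlier spots kept moved no main result by this measure. List medians whose interval spanned 0 nevertheless changed sign under some settings, such as germline genes in the array labelled as re-expressing against wildtype at -0.03 under quantile normalization. Members measured on both arrays only, and a return read from a second probe (66.7%), moved none either. Over all alternatives the return ran from 60.2% to 71.1%. Both filters on dim genes changed the counts, which they do by adding or removing genes. Below, counts are higher then lower, R is the array labelled as re-expressing, and the cause was not tested unless the setting itself adds or removes genes.

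Bright genes only, which removes genes, gave 126 and 95 for Pcgf6KO against wildtype, 127 and 252 for R against Pcgf6KO, and 89 and 144 for R against wildtype. Genes standing apart were 43 and 21 for wildtype, 93 and 25 for Pcgf6KO, and 50 and 102 for R. Germline members were 10 and 1, 0 and 10, and 1 and 0 in the 3 comparisons, and lower fibroblast markers 8, 5 and 13. List medians became 0.078 and -0.18 for endoderm genes in R against Pcgf6KO and wildtype, -0.25 and 0.39 for 2-cell genes in Pcgf6KO against wildtype and R against Pcgf6KO, and 0.27 for interferon-stimulated genes in R against wildtype.

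No filter on dim probes, which adds genes, gave 1590 and 879, 1967 and 2201, and 1764 and 1508. Genes standing apart were 451 and 330 for wildtype, 991 and 269 for Pcgf6KO, and 1203 and 975 for R. The return was 60.2% and the correlation of differences -0.46.

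The 1.5-fold threshold gave 1749 and 1130, 1812 and 2129, and 1551 and 1553, with 363 and 363, 1013 and 467, and 982 and 1062 standing apart. Lower germline members and higher fibroblast markers in Pcgf6KO against wildtype were 5 and 1, and higher germline members in R against wildtype 6. The 3-fold threshold gave 318 and 145, 233 and 567, and 220 and 260, with 48 and 18, 159 and 16, and 112 and 146 standing apart. Higher germline members in R against Pcgf6KO were 2, and in R against wildtype 0 higher and 0 lower.

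Normexp gave 453 higher genes and 0 lower germline members in R against wildtype. Genes standing apart were 48 lower for wildtype, 67 lower for Pcgf6KO and 280 higher for R. The 75th percentile of probes measured on all arrays gave 1 higher fibroblast marker in Pcgf6KO against wildtype. The mean over probes gave 1 lower germline member in R against wildtype, and Zfp467 at -0.80 against Pcgf6KO and -0.89 against wildtype.

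The deposited table without scaling shifted the median of all genes to 0.11, 0.13 and 0.22 in the 3 comparisons. Pcgf6 was then -0.90 in Pcgf6KO and -1.21 in R against wildtype. It gave 1 higher fibroblast marker in Pcgf6KO against wildtype, and 1075 and 450 genes with 6 and 0 germline members in R against wildtype. Wildtype stood apart in 95 and 171. List medians in Pcgf6KO against wildtype were 0.15 for stress response, 0.65 for Y-linked, -0.087 for immediate early and -0.0062 for glycolysis and hypoxia genes. In R against wildtype they were 0.17 for PRC1.6, 0.25 for other PRC1, 0.32 for germline, 0.26 for p53, 0.37 for stress response, 0.32 for interferon-stimulated, 0.33 for housekeeping and 0.37 for glycolysis and hypoxia genes.

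Where 2 probes had to pass, which only 3664 genes could, 12 and 8 genes stood apart for wildtype, 43 and 7 for Pcgf6KO, and 14 and 41 for R.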

Other observations

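The test of neighbouring genes was set before its result was seen. Within several lists, single members lay far from the list median. Among endoderm genes, Afp, the alpha-fetoprotein gene, was higher by 2.72 in Pcgf6KO than in wildtype, Dab2 by 1.26 and Amn by 1.13, whereas Cubn was lower by -1.88. T, the brachyury gene, was higher by 1.07 in Pcgf6KO and lower by -2.06 on the array labelled as re-expressing. Fgf5, a marker of the epiblast, was higher by 1.85 in Pcgf6KO, and Sox3 was lower by -2.56 on the array labelled as re-expressing than in wildtype. The immediate early gene Fosb differed by -1.13 in Pcgf6KO against wildtype and by 1.85 on the array labelled as re-expressing against Pcgf6KO.

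Genes higher in Pcgf6KO lay next to one another more often than under random placement, although most had no such neighbour. In the gene order of GRCm38.p6, used only for which genes are neighbours, 77 pairs of adjacent measured genes were both at least 2-fold higher. Pairs of one family name and pairs with a predicted gene were left out. Random placement of the 869 higher genes among 14997 gave 32 to 56 such pairs (central 95% of 10000 placements), so uniform random placement is argued against. The placements were not matched on expression, whereas bright genes only gave 126 higher genes. Neighbours of similar expression level may therefore also raise the number of pairs. With family pairs and predicted genes included there were 144 pairs against 37 to 64. Examples were Il18 and Tex12 with 2.33 and 2.45, and Tspan8 and Taf7l2 with 1.92 and 1.83, all named after their values were seen. That neighbours share a local change is a hypothesis, and related genes with unlike names, such as the globin genes Hba-a2 and Hbq1a with 1.63 and 1.70, may raise the 77 pairs.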
